A study of Arabidopsis thaliana with 10 samples.

How the data were processed

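Transcript levels were measured in rosettes of 4-week-old Arabidopsis thaliana plants (ecotype Col-0) on 10 Affymetrix ATH1 arrays. Per the labels' protocols, RNA was extracted with a Qiagen kit and labelled with biotin by the one-cycle method, and plants grew untreated in a room chamber at 50% humidity and 22 °C. The arrays form 4 groups, homozygous and heterozygous plants of a CesA4 line (3 arrays each) and of a CesA6 line (2 arrays each). Wild-type plants were not analysed here, so the heterozygous plants of the same line were the reference. The labels do not say whether replicates were separate plants, pools or labelings of shared RNA, so n counts arrays.

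The deposited values are intensities on a linear scale, MAS5 signals from the GCOS software per the submitters' processing notes. The deposited table holds 22810 probe sets, of which 64 are controls of the array maker. The 2% trimmed mean of every deposited array was 100.01 and the medians ran from 32 to 37.68, so the arrays had been scaled to a common level. No detection calls were used here. The 8 genes drawn by array were chosen after their values were seen.

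Each array was scaled to a 2% trimmed mean of 500, a pseudocount of 16 was added and log2 was taken. The pseudocount equals 3.2 on the deposited scale. A fold change is therefore on the log2(signal + pseudocount) scale, which understates the change of dim probe sets. A change is called shrunken where a group's mean lies below the pseudocount. It remains an estimate with a standard error, not a bound. Control probe sets and the 30% of probe sets with the lowest mean over all arrays were left out, which left 15922 probe sets. Changes were fitted with limma (version 3.58.1, R 4.3.3) with a mean for each of the 4 groups, all 10 arrays sharing the estimate of the spread, and eBayes with trend and robust. The fit had 6 residual degrees of freedom and a median of 16 prior ones. Adjusted p-values are limma's, by Benjamini-Hochberg over the probe sets tested, with a threshold of 0.05. The comparisons were homozygous minus heterozygous in each line, the difference between those changes, and the CesA4 line minus the CesA6 line over both genotypes with each group weighted equally. Errors of log2 changes are standard errors of the fit, and errors of mean signals are SDs between arrays on the deposited scale.

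Probe sets were named from the platform annotation of GEO. It listed 13513 probe sets with 1 gene, 503 with several and left 8730 unnamed. Of those with 1 gene, 13436 were matched by gene ID to the reference TAIR10.1, which gave the current symbol and locus, and 77 were not. Among the tested probe sets 8737 had 1 gene. The reference was used for names only, so no coordinates are given. CESA4, CESA6 and COBL4 had no named probe set, so the mutated genes could not be checked and are not analysed here.

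Before the data were examined, 28 gene lists with 497 entries by locus were fixed. Named probe sets covered 75 of the entries and 64 were tested, so 4 lists reached the minimum of 4 tested members and the rest are given as values. Lists were tested with camera against all other tested probe sets with a preset correlation of 0.01, adjusted over the testable fixed lists, and again with an estimated correlation. A further 28 lists were built from symbol patterns in the annotation before any change was computed, and 26 of them had at least 4 tested members. Their assignment to organelles was corrected after first results were seen. The patterns let in a peptide deformylase gene (PDF1B) among the defensins and the gene SEC among the exocyst genes. That the fixed and the added lists be adjusted as separate families was also decided after a first joint run, so the joint value is given where it ends a call. A gene with several probe sets was represented by the brightest.

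The rule for naming genes was also fixed beforehand. It took, per comparison and direction, the 8 named genes with the largest change among those past the threshold whose groups did not overlap, the 4 members with the smallest p of each called list, and up to 2 members of each other list. For the difference between lines, non-overlap meant that all pairwise homozygous minus heterozygous differences of a line lay on the same side of those of the other line, a definition made after the values were in hand.

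The fit was tested on simulated data, with the own means and residual SDs of the 15922 probe sets, of which 67, 67 and 66 were given log2 changes of 0.5, 1 and 2 per comparison. A log2 change of 1 was recovered for 41.8% of the changed probe sets in the CesA4 comparison, 25.4% in the CesA6 comparison, 4.48% in the difference between lines and 56.7% in the line comparison. A log2 change of 2 was recovered for 78.8%, 74.2%, 48.5% and 86.4% in the same order. Between 2 and 4 unchanged probe sets were called per comparison. The simulations gave 37 to 105 calls, fewer than the data, so the threshold was stricter and the recovery need not carry over. Noise was drawn separately for each probe set, so false calls under correlation between genes were not covered. Alternatives were quantile normalization, the deposited signal without rescaling (which keeps the pseudocount and so acts as a larger pseudocount, not as a check of scaling), pseudocounts of 1 and 64, no filter, a filter at 50%, eBayes without trend and robust, array weights, the replicate number as a block, leaving out each array, and fits to the arrays of a line alone.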

Results

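Gene expression was profiled in rosette leaves of Arabidopsis plants of 2 lines that the labels name after the cellulose synthase genes CesA4 and CesA6. CESA4 is a subunit of the complex that makes cellulose of secondary walls, and CESA6 a subunit of the primary wall complex. The data comprised 10 arrays, with 3 homozygous and 3 heterozygous CesA4 arrays and 2 homozygous and 2 heterozygous CesA6 arrays. The labels give the CesA4 allele as irx5-2. They call the other line both CesA6 and irx6-1, while the reference lists IRX6 as a name of COBL4, a different gene. The line is called CesA6 here, short for the AtCesA6 of the labels, which leaves open which gene is mutated. CESA4, CESA6 and COBL4 had no named probe set and their levels are not analysed here, so the genotypes were not checked against the transcripts. Correlations between replicate arrays of a group ran from 0.935 to 0.954, against 0.874 for the least similar pair of arrays. The first principal component held 34.2% of the variance and had homozygous arrays of both lines on its negative side and all heterozygous arrays on its positive side. The second held 15.2% and separated the lines.

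The first comparison asked which transcripts differ between homozygous and heterozygous plants of the CesA4 line. Among the genes higher in homozygous plants were AT3G02480, AT3G17520 and LEA4-5 of the late embryogenesis abundant (LEA) family, which encodes proteins made in drying tissue. AT3G02480 had a signal of 970.8 ± 116 in homozygous and 31.27 ± 2.61 in heterozygous plants (SD, n = 3 each), a log2 change of 4.82 ± 0.16 (SE, adjusted p = 3.6e-15). AT3G17520 was higher by 3.58 ± 0.35 on the log2 scale and LEA4-5 (AT5G06760) by 3.48 ± 0.19. BSMT1 (AT3G11480), a methyltransferase that makes methyl salicylate and methyl benzoate, was higher by 4.56 ± 0.33, with a signal of 663.5 ± 116 against 27.06 ± 14.6. The lipid-transfer-type gene AT3G53980 was higher by 4.23 ± 0.25. AT3G28270, AT1G09500 and the GDSL-lipase gene AT1G54020 had log2 changes of 3.93 ± 0.17, 3.52 ± 0.46 and 3.35 ± 0.29. EXO had among the largest falls. EXO (AT4G08950), a brassinosteroid-responsive gene of leaf growth, went from 1635 ± 317 in heterozygous to 30.24 ± 19.9 in homozygous plants, a log2 change of -5.85 ± 0.56 (adjusted p = 0.000389). The expansin-like gene EXLA1 (AT3G45970) changed by -3.97 ± 0.25, from 856.1 ± 140 to 52.71 ± 16.1. The AP2/ERF transcription factor genes AT1G77640 and AT1G33760 changed by -3.68 ± 0.48 and -3.59 ± 0.59. The aspartyl-protease-family gene AT4G16563, the TIR-domain gene AT3G04210, AT1G50040 and AT4G37240 changed by -4.26 ± 0.49, -4.15 ± 0.34, -4.42 ± 0.62 and -3.87 ± 0.43. The falls of AT1G50040 and AT1G33760, and that of XTH33 below, are shrunken estimates, since the homozygous signal lay below the pseudocount. The probe sets with the largest rise and the largest fall of all are not named in the annotation used here.

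**Figure D1:**
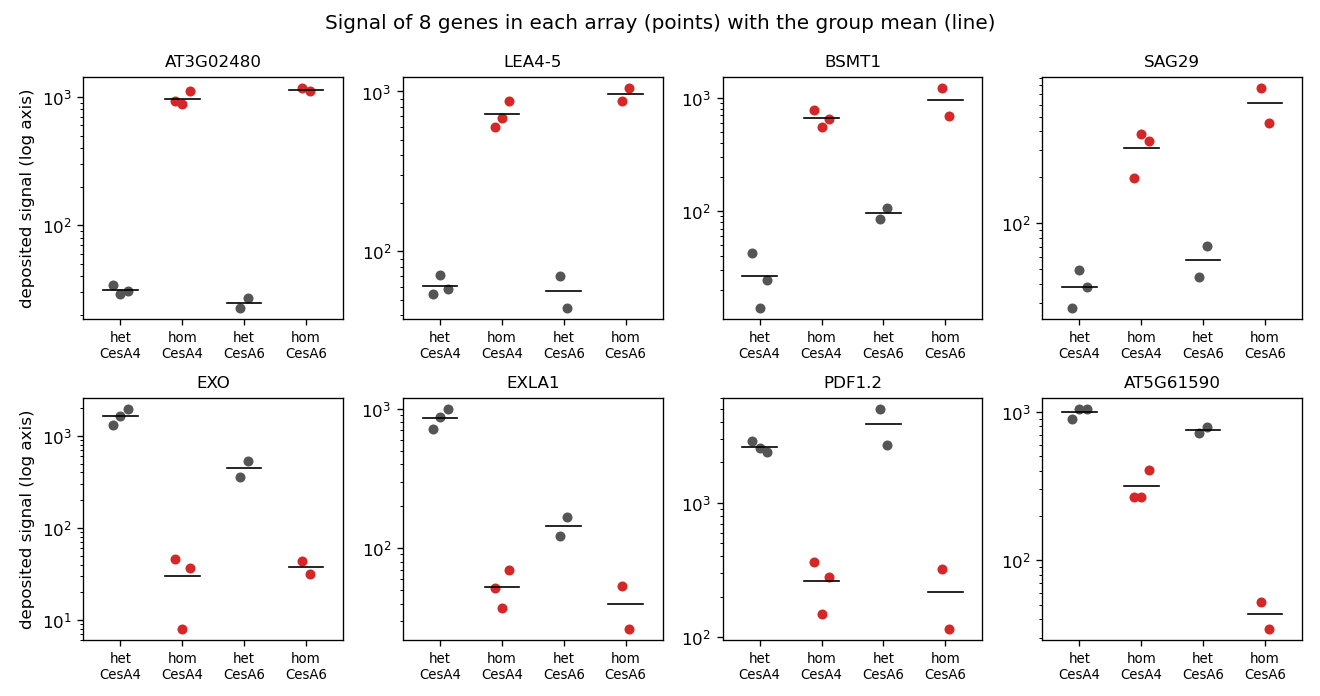
Deposited signal (log axis) of 8 genes named in the text in each array, with heterozygous arrays in grey, homozygous arrays in red and the group mean as a line. AT3G02480 averaged 970.8 and 1142 in homozygous CesA4 and CesA6 plants and 31.27 and 24.82 in heterozygous ones, and AT5G61590 averaged 314.3 and 43.29 in the homozygous groups.

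Of the 30 genes listed for abscisic acid, drought and cold responses, 5 were tested, and these rose as a group in the CesA4 line. They are the LEA, dehydrin and cold-regulated genes named below, so the other listed genes are not covered. Of the 5 tested members 4 passed, all higher (5 adjusted over the list alone), with a median log2 change of 0.93. Besides LEA4-5 these were the dehydrin gene LTI30 (AT3G50970), at 1.90 ± 0.15, and the cold-regulated chloroplast protein genes COR15A (AT2G42540) and COR15B (AT2G42530), at 0.87 ± 0.14 and 0.93 ± 0.17. COR47 (AT1G20440), also a dehydrin, stood at 0.28 ± 0.12 and did not pass. All 5 tested genes of anthocyanin and flavonoid synthesis were higher (5 adjusted over the list alone), with a median of 1.01. The anthocyanin glucosyltransferase gene AT4G14090 rose from 252.6 ± 26.1 to 624.7 ± 50.5, DFR (AT5G42800) by 1.01 ± 0.16, UF3GT (AT5G54060) by 1.05 ± 0.17 and UGT78D2 (AT5G17050) by 0.66 ± 0.16. Among 11 xyloglucan endotransglucosylase, expansin and expansin-like genes 5 were lower and none higher (6 lower and 1 higher adjusted over the list alone). These families encode wall-loosening and wall-remodelling proteins and are called the wall-loosening list for short, although loosening was not measured. Their median of -1.21 became -0.42 with the lowest 50% of probe sets left out and -0.79 on the deposited scale. Besides EXLA1 the lower genes included EXLA2 (AT4G38400) at -2.02 ± 0.24, XTH16 (AT3G23730) at -1.87 ± 0.24 and XTH33 (AT1G10550) at -3.37 ± 0.62. By camera the adjusted p was 4.25e-07 for the abscisic acid list, 6.45e-06 for the anthocyanin list and 0.000218 for the wall list. With an estimated correlation the 3 calls held, at 0.023, 0.0389 and 0.023. Photosynthesis genes were not called (adjusted p = 0.241), and of 8 tested only SBPASE (AT3G55800) passed, at -0.41 ± 0.12.

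Lists with fewer than 4 tested members give single-gene values for the CesA4 line. IRX15-L (AT5G67210), a gene of xylan synthesis in secondary walls, rose by 1.72 ± 0.18, from 47.52 ± 9.36 to 161.9 ± 1.68. CCR2 (AT1G80820) and HCT (AT5G48930) of the lignin pathway rose by 1.59 ± 0.26 and 0.47 ± 0.14. COB (AT5G60920), needed for oriented cellulose deposition, fell by 0.61 ± 0.13 on the log2 scale, and the wall-sensing receptor kinase THE1 (AT5G54380) fell by 1.61 ± 0.22. The receptor kinase AT4G08850 changed by -1.06 ± 0.21. The jasmonate-inducible thionin gene THI2.1 (AT1G72260) rose from 226.2 ± 76.4 to 956.6 ± 247, while the defensin genes PDF1.2 (AT5G44420) and PDF1.2b (AT2G26020) changed by -3.40 ± 0.48 and -2.86 ± 0.61. Of the senescence list, the sugar transporter gene SAG29 (AT5G13170) rose by 2.89 ± 0.28 and WRKY6 (AT1G62300) by 1.58 ± 0.40. WRKY53 (AT4G23810), of the salicylate list, changed by -2.52 ± 0.25. PYK10 (AT3G09260), a root-expressed beta-glucosidase, stood at 1.02 ± 0.34 and did not pass (adjusted p = 0.0736).

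In all, limma called 2410 of the 15922 probe sets in the CesA4 line, 1306 higher and 1104 lower in homozygous plants, and 1112 of them changed at least 2-fold. Among called genes with a name the groups did not overlap for 602 of 626 higher and 501 of 518 lower genes, where chance gives 10% for genes not already chosen by a test. PDF1.2b lost its call without homozygous CesA4 replicate 2 or 3 and without heterozygous CesA4 replicate 1 or 2, and the call was lost in 5 alternatives for SBPASE, 4 for HCT and 2 for UGT78D2.

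The second comparison asked the same of the CesA6 line. AT3G02480 and AT3G17520 of the LEA family were among the genes with the largest rise. AT3G02480 went from 24.82 ± 3.37 in heterozygous to 1142 ± 38.4 in homozygous plants (SD, n = 2 each), a log2 change of 5.36 ± 0.20 (SE, adjusted p = 2.83e-14). AT3G17520 was higher by 4.44 ± 0.43 and LEA4-5 by 4.03 ± 0.23. The calmodulin-like gene AT1G76640 was higher by 4.12 ± 0.55, and the lipid-transfer-type gene AT1G62510 by 3.61 ± 0.29. AT3G28270, AT1G09500 and the strictosidine-synthase-like gene AT3G57010 had log2 changes of 3.91 ± 0.20, 3.79 ± 0.56 and 3.40 ± 0.55. The defensin gene PDF1.2 had among the largest falls. PDF1.2, from 3843 ± 1620 to 216.4 ± 145, changed by -4.24 ± 0.59 (adjusted p = 0.00523) and PDF1.2b by -3.74 ± 0.75. AT5G61590, an ERF transcription factor gene that represses wax synthesis, fell from 751.2 ± 51.6 to 43.29 ± 12.8, a log2 change of -4.05 ± 0.22 (adjusted p = 2.51e-11). SUFE2 (AT1G67810), of iron-sulphur cluster assembly, changed by -3.67 ± 0.59, AT3G04210 by -3.54 ± 0.41 and EXO by -3.43 ± 0.68. AT4G11000 and the calcium-binding protein gene AT4G27280 changed by -3.32 ± 0.83 and -3.16 ± 0.21. The values of AT3G17520, AT1G09500 and AT4G11000 are shrunken estimates, since a group lay below the pseudocount. The PDF1.2b call was lost in 6 alternatives, the EXO call in 5 (each CesA6 array left out among them), the AT4G11000 call in 3 and the PDF1.2 call in 1, a fit to the CesA6 arrays alone.

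All 5 tested genes of the abscisic acid, drought and cold list rose in the CesA6 line (5 adjusted over the list alone), with a median log2 change of 1.54. LTI30 rose by 1.69 ± 0.18, COR15A by 1.54 ± 0.17 and COR47 by 0.97 ± 0.15, beside LEA4-5. The camera adjusted p was 1.75e-12, and 0.00574 with an estimated correlation. Of the 11 genes of the wall-loosening list 2 were lower (3 adjusted over the list alone), XTH16 at -1.74 ± 0.30 and EXLA1 at -1.84 ± 0.30. EXPA8 (AT2G40610) and EXLB1 (AT4G17030) stood at -1.50 ± 0.48 and -0.62 ± 0.27 and did not pass. That list had a median of -0.54 and a camera adjusted p of 0.00911, which became an adjusted p of 0.071 with an estimated correlation. None of the 5 anthocyanin and flavonoid genes passed (2 higher adjusted over the list alone). Their median was 0.35 (0.20 to 0.49 over the alternatives), with UGT78D2 at 0.58 ± 0.19, AT4G14090 at 0.48 ± 0.18, UF3GT at 0.35 ± 0.21 and DFR at 0.27 ± 0.20. Camera called the list as higher (adjusted p = 0.0257), but not with an estimated correlation (adjusted p = 0.269) nor when adjusted together with the added lists (adjusted p = 0.144), and the call was lost in 4 of 21 alternatives. None of the 8 photosynthesis genes passed, and the list was not called (adjusted p = 0.203).

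**Figure D2:**
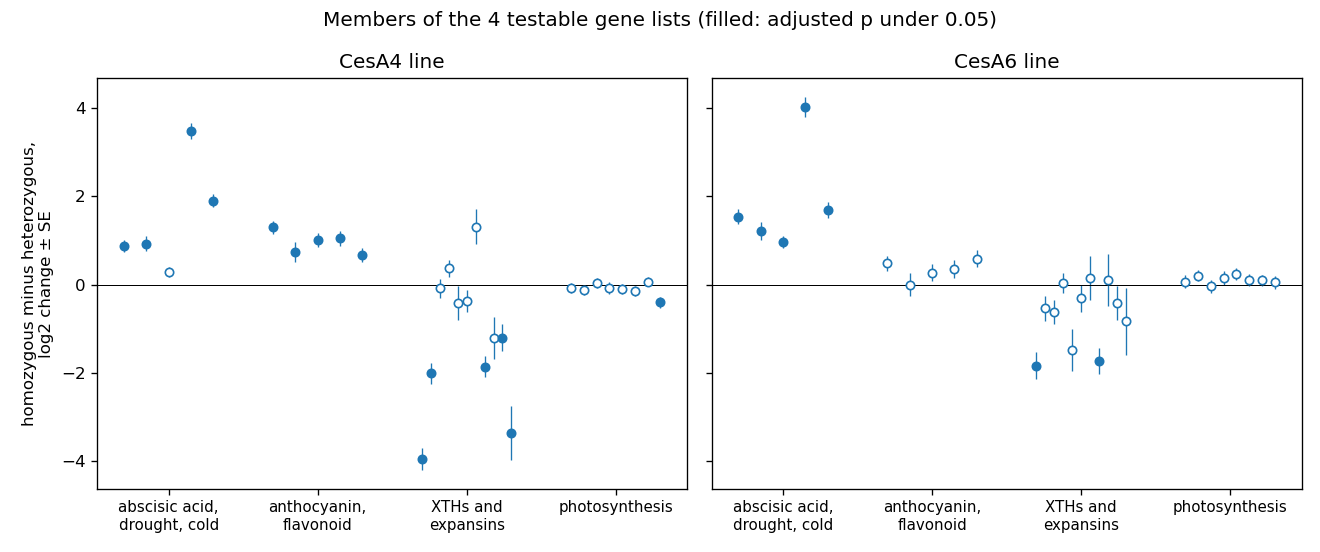
Log2 change (homozygous minus heterozygous, ± SE) of each tested member of the 4 testable gene lists in the CesA4 line (left) and the CesA6 line (right), with members past an adjusted p of 0.05 filled. The abscisic acid list had medians of 0.93 and 1.54, and the wall-loosening list of xyloglucan endotransglucosylases (XTHs) and expansins had medians of -1.21 and -0.54.

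Among genes of the shorter lists in the CesA6 line, CCR2 rose by 1.37 ± 0.32, THI2.1 by 2.50 ± 0.30 and SAG29 by 3.32 ± 0.34. THE1 changed by -1.25 ± 0.26, AT4G08850 by -1.32 ± 0.26, WRKY53 by -1.94 ± 0.30 and the zinc-finger stress gene STZ (AT1G27730) by -1.66 ± 0.21. The CCR2 call was lost in 3 alternatives and the AT4G08850 call in 1. IRX15-L stood at 0.16 ± 0.23 and COB at -0.41 ± 0.16, and neither passed. PYK10 stood at 1.52 ± 0.41 and did not pass. In all, limma called 1358 probe sets, 593 higher and 765 lower in homozygous plants, and 861 of them changed at least 2-fold. All 270 higher and 346 lower named genes that passed had groups that did not overlap, where chance gives 33.3% for genes not already chosen by a test. The count was 717 without homozygous CesA6 replicate 2, 777 without heterozygous CesA6 replicate 1, 789 without heterozygous CesA6 replicate 2, and 747 with eBayes without trend and robust.

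The changes of the lines were then set side by side, each line having its own heterozygous reference. Genes that passed in both lines included AT3G02480, AT3G17520, LEA4-5, BSMT1, AT3G28270, SAG29 and THI2.1 among the higher ones and EXO, EXLA1, XTH16, PDF1.2, THE1 and WRKY53 among the lower ones. In total 443 probe sets were higher in both lines and 442 lower in both, where independent lists of the same lengths would share 48.64 and 53.04. The comparisons share an estimate of the spread for each probe set, so more sharing than this can arise without a common response, though with neither sign favoured. Opposite signs were seen for 7 probe sets that passed in both. Of the 1358 calls of the CesA6 line, 1258 (92.6%) had the same sign in the CesA4 line. Across the 15922 probe sets, which are not independent replicates, Pearson's r between the log2 changes was 0.55 and Spearman's rho 0.391. The number shared with the same sign, 885, became 573 without homozygous CesA6 replicate 2 and 518 with eBayes without trend and robust.

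**Figure D3:**
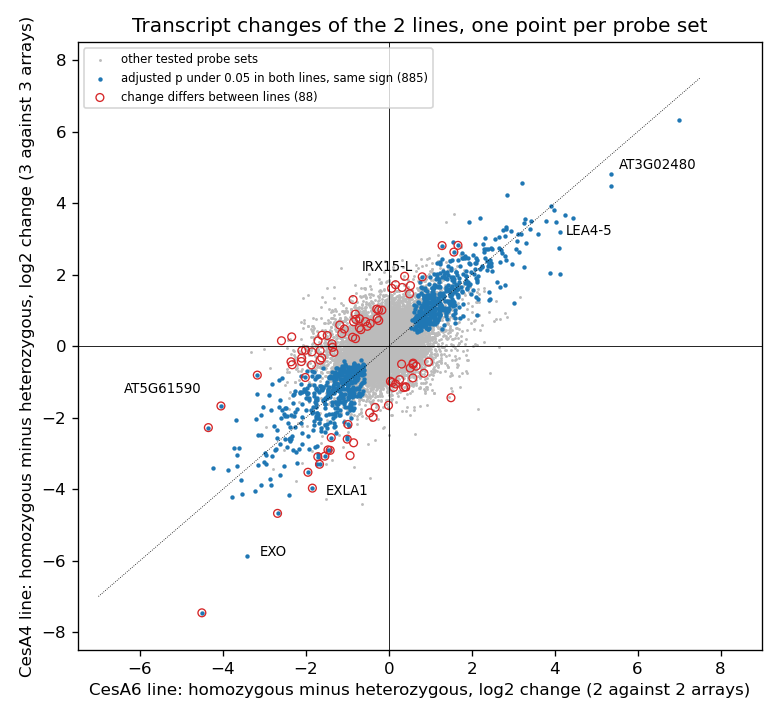
Log2 change (homozygous minus heterozygous) of each of the 15922 tested probe sets in the CesA6 line (horizontal) and the CesA4 line (vertical), with the dotted line marking equal change. The 885 probe sets that passed in both lines with the same sign are blue, and the 88 whose change differed between lines are circled in red.

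The third comparison asked which changes differ between the lines, as the CesA4 change minus the CesA6 change. AT5G61590 fell in both lines but by less in the CesA4 line, from 990.7 ± 84.5 to 314.3 ± 80.5, a difference of 2.38 ± 0.28 on the log2 scale (adjusted p = 0.000223). The AP2/ERF gene ORA47 (AT1G74930), a regulator of jasmonate synthesis, differed by 2.17 ± 0.37, with 110.4 ± 25.8 in homozygous and 42.43 ± 7.27 in heterozygous CesA4 plants (n = 3 each) and 39.93 ± 12.1 and 73.62 ± 5.37 in the CesA6 groups (n = 2 each). The glutaredoxin-family gene AT3G62950 differed by 2.74 ± 0.63, the photosystem II subunit gene psbK by 1.92 ± 0.37 and the jacalin-related lectin gene JAL23 by 1.58 ± 0.34. AT2G24550, AR781 and AT3G10020 differed by 1.97 ± 0.32, 1.77 ± 0.32 and 1.70 ± 0.29. IRX15-L and STZ, each from a shorter list, differed by 1.56 ± 0.29 and 1.27 ± 0.28. In the other direction EXLA1 fell by more in the CesA4 line, with a difference of -2.13 ± 0.39 (adjusted p = 0.0172). AT5G03120, AT5G44020, AT2G47440, AT2G30930 and AT2G34510 differed by -2.13 ± 0.43, -1.63 ± 0.34, -1.53 ± 0.27, -1.50 ± 0.32 and -1.44 ± 0.31. The GDSL-lipase gene AT4G18970 and the TIR-type resistance gene AT4G19530 differed by -1.65 ± 0.37 and -1.61 ± 0.31. The AT3G62950 call was lost in 14 of 19 alternatives, with quantile normalization (adjusted p = 0.061) among them, the JAL23 call in 10, the AT4G18970 call in 9, the AT5G44020 and AT2G34510 calls in 8 each, the STZ call in 9, the IRX15-L call in 4, and those of the other 11 genes with the largest differences in 1 to 7. The AT3G62950 value rests on a shrunken CesA6 change, since its signal in homozygous CesA6 plants lay below the pseudocount.

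As groups, anthocyanin genes had the higher change in the CesA4 line (median difference 0.74, camera adjusted p = 0.0028), and the abscisic acid list (-0.55, adjusted p = 0.00908), the photosynthesis list (-0.24, adjusted p = 0.0165) and the wall-loosening list (-0.13, adjusted p = 0.0409) had the lower. None of these calls held with an estimated correlation, where the adjusted p was 0.133 for the anthocyanin, abscisic acid and wall-loosening lists and 0.197 for photosynthesis. Adjusted over the list alone, 3 anthocyanin genes were higher, and 2 genes of the abscisic acid list and 2 of the wall-loosening list lower. EXLA1 was the only member of the 4 lists to pass over all probe sets, and COR47, AT4G14090 and SBPASE stood at -0.69 ± 0.19, 0.82 ± 0.23 and -0.45 ± 0.19. Adjusted together with the added lists, the photosynthesis list (adjusted p = 0.0714) and the wall-loosening list (adjusted p = 0.154) also lost their calls. The median of the wall-loosening list ran from -0.41 to 0.03 over the alternatives, so its sign turned. Of 20 alternatives 11 ended the wall-loosening call, 6 the photosynthesis call, 2 the abscisic acid call and 1 the anthocyanin call. In all, limma called 88 probe sets, 53 with the higher and 35 with the lower change in the CesA4 line. The count was 41, 39 and 39 without homozygous CesA4 replicate 1, heterozygous CesA4 replicate 1 or heterozygous CesA4 replicate 3, and 17, 14 and 19 without homozygous CesA6 replicate 2, heterozygous CesA6 replicate 1 or heterozygous CesA6 replicate 2. It was 0 with eBayes without trend and robust in limma, where 1629 probe sets had an unadjusted p under 0.05, against 1903 in the fit used here.

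The last comparison set the CesA4 line against the CesA6 line over both genotypes. A processing difference that went with line was not tested and cannot be told apart from line here. Named genes lower in the CesA4 line included AT2G33850 and AT3G47480, and AT1G71000 was among those higher. The receptor-like kinase gene AT1G35710 had signals of 40.29 ± 8.07 and 89.03 ± 18.3 in homozygous and heterozygous CesA4 plants (n = 3 each) and 160.7 ± 34.1 and 621.8 ± 142 in the CesA6 groups (n = 2 each), a log2 difference of -2.34 ± 0.16 (adjusted p = 9.23e-09). The calcium-binding protein gene AT3G47480 differed by -2.54 ± 0.21, the chitinase-family gene CHI (AT2G43570) by -1.98 ± 0.20 and the TIR-domain gene AT1G57630 by -1.99 ± 0.44. AT2G33850, the GDSL-lipase gene AT5G33370, SAL2 (AT5G64000) and AT4G00700 differed by -2.64 ± 0.16, -2.50 ± 0.50, -2.11 ± 0.47 and -1.97 ± 0.42. The DnaJ-type chaperone gene AT1G71000 was higher in the CesA4 line by 2.66 ± 0.43, with 60.31 ± 7.45 and 12.88 ± 4.96 in homozygous and heterozygous CesA4 plants and 1.01 ± 0.35 and 2.77 ± 1.61 in the CesA6 groups. AT1G23000, AT3G59350, AT5G62360 and AT3G01380 were higher by 1.64 ± 0.46, 1.62 ± 0.20, 1.51 ± 0.20 and 1.45 ± 0.34, and AT4G28180, AT1G23410 and AT1G22550 by 1.45 ± 0.35, 1.42 ± 0.38 and 1.38 ± 0.25. The values of AT1G71000 and AT1G23000 are shrunken estimates, since at least 1 CesA6 group lay below the pseudocount. The AT1G23410 call was lost in 12 of 19 alternatives, and its value was 0.75 without homozygous CesA6 replicate 2. The call was lost in 9 alternatives for AT1G23000, 4 for AT1G57630, 3 each for AT3G01380 and AT4G28180, and 1 each for AT1G71000, SAL2 and AT4G00700.

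In this comparison the tested genes of the abscisic acid, drought and cold list were higher in the CesA4 line, 4 of 5 passing (4 adjusted over the list alone). LTI30 stood at 0.87 ± 0.12, COR47 at 0.57 ± 0.09, COR15B at 0.73 ± 0.13 and COR15A at 0.42 ± 0.11. The COR15A call was lost in 7 alternatives and the COR15B call in 1. Camera gave an adjusted p of 4.92e-05, and an adjusted p of 0.0614 with an estimated correlation. Anthocyanin genes were lower as a list (camera adjusted p = 0.0146, and adjusted p = 0.202 with an estimated correlation), with DFR at -0.55 ± 0.13 the only member to pass (3 adjusted over the list alone), a call lost in 4 alternatives. The anthocyanin list call was lost in 4 of 20 alternatives. Of the wall-loosening list 3 genes were higher (3 higher and 1 lower adjusted over the list alone), among them EXLA1 at 1.48 ± 0.19 and EXLA2 at 0.95 ± 0.19. By camera the list was not called (adjusted p = 0.0718), nor was photosynthesis (adjusted p = 0.855). In all, limma called 1074 probe sets, 420 higher and 654 lower in the CesA4 line. Among called genes with a name, 46 of 182 higher and 86 of 298 lower ones separated all 6 CesA4 from all 4 CesA6 arrays, where chance gives 0.952% for genes not already chosen by a test. The count was 662 without homozygous CesA6 replicate 1, 499 without heterozygous CesA6 replicate 1 and 428 with eBayes without trend and robust.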

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

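The tests of RNA integrity, their reading for each line, the dismissal of the line-label splits, and the comparison with the heterozygous arrays used to weigh a lone homozygous CesA6 array, were chosen after the results they bear on had been seen.

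The first pattern is that homozygous minus heterozygous changes ran the same way in both lines, with r = 0.5503 across probe sets and 885 shared calls. A chance division of the arrays is argued against, since of 30 ways to split the arrays only the real 1 reached that correlation (highest other 0.3634). Differences in signal distribution left by the scaling are argued against too, since 845 of the 885 calls stayed after quantile normalization. Both procedures set the arrays to a common level, so a shift in total RNA that went with genotype was not tested. Of the 885 calls 81.58% (95% CI 78.87 to 84.08) lay among the tested probe sets brighter than the median. That was the outcome predicted without noise of dim probe sets, but passing the threshold favours bright probe sets, so this share cannot decide. The correlation rose to 0.692 with the lowest 50% of probe sets left out, which argues against noise of dim probe sets as its source. Lower RNA integrity is argued against in the homozygous CesA4 arrays, where the 3' to 5' ratios of actin and GAPDH differed by 0.002 ± 0.128 and 0.087 ± 0.133 (SE, log2; higher upper bound 0.353, below the 0.58 of a 1.5-fold loss), but cannot be told apart in the homozygous CesA6 arrays (n = 2), at 0.151 ± 0.172 and 0.282 ± 0.242 (upper bound 0.766). The homozygous genotype shared by these groups stays open, as does any growth or handling difference that went with genotype, and neither was tested.

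The second pattern is the 88 probe sets whose change differed between lines by the interaction test. A chance division of the line labels cannot be told apart: 6 of 100 ways to share them out within genotypes, the real 1 included, gave at least 88 (up to 621), which meets the criterion set beforehand, but such splits carry the line difference and are no null for this count. Of the 5 others, 3 put both homozygous CesA6 arrays (449 to 621) and 1 both heterozygous CesA6 arrays under the CesA4 label with no other array of that line moved, and the remaining 1 gave 95. For an undue weight of homozygous CesA6 replicate 2, the criterion set beforehand was met, as 15 of the 88 calls stayed without it and 55 without replicate 1. Leaving out heterozygous CesA6 replicate 1 or 2 left 12 and 18, a comparison added after that result was seen, so this array cannot be told apart from a general loss of power with 3 CesA6 arrays, and a biological difference between the lines stays open.

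The named genes flagged by the same test were, with the higher change in the CesA4 line, AT3G62950 (2.74), AT5G61590 (2.38), ORA47 (2.17), AT2G24550 (1.97), psbK (1.92), AR781 (1.77), AT3G10020 (1.70) and JAL23 (1.58). With the lower change in the CesA4 line they were EXLA1 (-2.13), AT5G03120 (-2.13), AT4G18970 (-1.65), AT5G44020 (-1.63), AT4G19530 (-1.61), AT2G47440 (-1.53), AT2G30930 (-1.50) and AT2G34510 (-1.44). Gene lists flagged by the camera test of the difference had an adjusted p of 0.0028 for anthocyanin and flavonoid synthesis, 0.00908 for abscisic acid, drought and cold, 0.0165 for photosynthesis, 0.0409 for xyloglucan endotransglucosylases and expansins and 0.0402 for autophagy genes. In the same order the adjusted p with an estimated correlation was 0.133, 0.133, 0.197, 0.133 and 0.763, so none held, and adjusted over fixed and added lists together photosynthesis (adjusted p = 0.0714) and the wall list (adjusted p = 0.154) were not called.

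The ubiquitin control probe sets, which are outside the tested ones, were flagged because every homozygous array stood above every heterozygous array of its line, with a fold of 1.37 for the 3' and 1.33 for the 5' probe set (mean of the lines). By line the fold was 1.49 (CesA4) and 1.26 (CesA6) for the 3' and 1.61 and 1.11 for the 5' probe set. The 3' signal was 5779 ± 276 against 3869 ± 266 in the CesA4 line and 6221 ± 831 against 4922 ± 84.7 in the CesA6 line (SD, n = 3 and n = 2 per group). The exact p of each was 0.0167, the smallest that 120 assignments allow, and 0.0668 adjusted over the 8 control measures.

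Of 10 splits of the CesA4 arrays only the real 1 gave as many calls as the 2410 found (highest other 0). As 10 splits cannot go below 5%, they cannot decide by themselves. Of these calls 2110 (87.55%) had the same sign in the CesA6 line, whose arrays are separate, though probe sets are not independent. With the agreement of the lines over 30 splits (0.5503, highest other 0.3634), this argues against a chance division of the CesA4 arrays. Of 100 ways to share out the line labels only the real 1 gave as many line differences as the 1074 found (highest other 264). Such splits cannot address a processing difference that went with line, which was not tested. The mean signal of the hybridization spike controls ran from 940 to 1124 in the CesA4 arrays and from 1207 to 1275 in the CesA6 arrays. No group held 4 arrays, so none was searched for a lone outlying array.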

How the results depend on the processing

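All alternatives in this part were planned; adjusting fixed and added lists together was chosen after a result had been seen. With eBayes without trend and robust the counts were 747 for the CesA6 line, 0 for the difference between lines, 428 for the line comparison and 518 shared with the same sign; the cause was not tested. With the replicate block the difference between lines gave 197 and the line comparison 571, the cause was not tested, and UGT78D2 in the line comparison went from -0.15 to 0.118. Same-numbered arrays had correlations of deviations of 0.014, 0.082 and 0.061 in the CesA4 line and 0.037 in the CesA6 line, all positive but small. Homozygous CesA4 replicates 2 and 3 correlated best with their own number, and replicate 1 with number 3 (0.027). The numbers were not taken to pair the samples, but a weak pairing cannot be excluded.

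Leaving out each array, which means fewer samples and in the CesA6 line leaves a lone array assumed to vary like the other groups, gave 1942 to 2351 calls for the CesA4 line, 717 to 1553 for the CesA6 line, 14 to 130 for the difference between lines, 499 to 1103 for the line comparison and 573 to 908 shared. COR15B in the difference between lines ranged from -0.61 to 0.052, reversing without heterozygous CesA6 replicate 1. Quantile normalization, other pseudocounts (the deposited scale acts as a larger pseudocount), other filters and array weights kept every count of probe sets within 1.5 times. For the difference between lines, the fixed lists called went from 4 to 2 with quantile normalization and with no filter, and the added lists from 1 to 2 (pseudocount 64, deposited scale, no filter) or 0 (50% filter); for the CesA4 line the added lists went from 5 to 3 with the 50% filter. Among named genes of these comparisons 52 of 66 values in the CesA4 line, 39 of 50 in the CesA6 line, 15 of 37 in the difference and 15 of 38 in the line comparison kept direction and side of the threshold throughout. In the same order 6, 3, 3 and 6 values that had not passed did so in at least 1 alternative. The fixed-list calls of the CesA4 line and the abscisic acid call of the CesA6 line held in all 21 alternatives. Dim probe sets limit what can be seen, since a signal near the pseudocount of 3.2 hides fold changes.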

Other observations

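The LEA list was written, and its test chosen, after the genes with the largest changes had been seen. The other lists here were built before any change was computed. Their assignment to organelles, on which the chloroplast-encoded list rests, was corrected after first results were seen.

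Further gene families, grouped by symbol, were called by camera in the CesA4 line with the preset correlation, and none with an estimated correlation. Chloroplast-encoded genes were lower as a list of 67 (median -0.44, from -0.66 to -0.27 over the alternatives, 1 passing, 0 adjusted over the list alone; adjusted p = 0.000112, and adjusted p = 0.595 with an estimated correlation). Tubulin genes were lower (median -0.40, 3 of 7, 5 adjusted over the list alone; adjusted p = 0.00869, and adjusted p = 0.595 with an estimated correlation), with TUB5 (AT1G20010) at -1.46 ± 0.17 and TUB1 (AT1G75780) at -1.16 ± 0.19. Defensins and related cysteine-rich proteins were lower (4 of 8 lower and 1 higher, the same adjusted over the list alone; adjusted p = 0.00991, and adjusted p = 0.279 with an estimated correlation). Xyloglucan endotransglucosylases alone were lower (3 of 5, 4 adjusted over the list alone; adjusted p = 0.00254, and adjusted p = 0.233 with an estimated correlation). Expansins and expansin-like genes alone were not called by camera in the CesA4 line (median -0.09, 3 of 12 lower, adjusted p = 0.266). They were not called in the CesA6 line either (adjusted p = 0.44). Autophagy genes were higher (2 of 10, 3 adjusted over the list alone; adjusted p = 0.0498, and adjusted p = 0.595 with an estimated correlation; lost in 12 of 21 alternatives), with ATG8F (AT4G16520) at 0.81 ± 0.14.

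In the CesA6 line only the chloroplast-encoded list was called (median -0.61, 4 of 67 lower, 4 adjusted over the list alone; adjusted p = 5.59e-06, and adjusted p = 0.673 with an estimated correlation; lost in 3 of 21 alternatives), and the median was -0.31 without homozygous and -0.15 without heterozygous CesA6 replicate 2, which end the call, and -1.09 without heterozygous CesA6 replicate 1. In this line psbK stood at -2.36 ± 0.28 and rpl33 at -1.52 ± 0.27. The difference between lines called autophagy genes (median 0.50, none passing; adjusted p = 0.763 with an estimated correlation; lost in 6 of 20 alternatives). Between lines, tubulins were higher in the CesA4 line (adjusted p = 0.00263, and adjusted p = 0.522 with an estimated correlation), and autophagy genes and cytochromes P450 lower (adjusted p = 0.00687 each, and adjusted p = 0.618 and 0.303 with an estimated correlation; each lost in 3 of 20 alternatives). Single family members that passed in both lines, with the CesA4 value first, were the glycosyltransferase gene UGT76E12 (3.29 and 2.84), the ubiquitin ligase gene PUB19 (2.21 and 3.25), the sugar transporter gene SWEET4 (2.71 and 2.39), the cell wall genes TBL37 (1.43 and 1.68), CSLA01 (1.64 and 1.88) and TBL45 (-1.44 and -1.73), and the tetraspanin gene TET8 (-1.52 and -1.58).

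A hypothesis formed here is that the rise of AT3G02480, AT3G17520 and LEA4-5 in both lines is part of a water-deficit-like response. It was tested on 5 other LEA-family genes, leaving out the fixed list and the genes named for their size. Their median was 0.16 in the CesA4 line (1 higher, camera p = 0.27) and 0.49 in the CesA6 line (2 higher, camera p = 0.00948, and p = 0.0688 with an estimated correlation). DI21 (AT4G15910) passed in both, at 1.24 ± 0.21 in the CesA4 line, while AT4G38410 stood at -1.29 ± 0.47 there and did not pass. The prediction asked for a rise in both lines, so this test cannot decide. LTI30 and COR15A, of the fixed list left out here, also passed in both lines, but they were not part of this test and do not change its outcome. Whether the rise of AT3G02480, AT3G17520 and LEA4-5 is part of a water-deficit-like response stays open.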
